A study of Mus musculus with 4 samples.

How the data were processed

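Droplet single-cell RNA sequencing had been run on neuroretina of mice with experimental autoimmune uveoretinitis, a model of eye inflammation induced by immunisation with the retinal protein IRBP. Per the labels, retinas were digested with 0.25% trypsin for about 30 min at 37 °C and passed through a 40 µm strainer. CD45-positive cells were taken with beads, about 5000 cells were loaded per library at a viability of about 90%, and cDNA was amplified for 10 cycles. There was 1 library for each of days 0, 14, 21 and 28. The labels do not state whether a library pools several mice, nor how barcodes were called as cells. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 2.1.1 from 10x Genomics Chromium 3′ v2 libraries against the mouse genome assembly GRCm38. The values are whole numbers, and each matrix holds 27998 genes. Cell classes were rebuilt here from the counts. Several marker and list genes are absent from the gene table, among them Clec7a, Cebpd, Trac, Trbc1, Trbc2, Ighm and Ighd, and were left out. Gene coordinates are from the GRCm38 annotation.

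The matrices were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, processed with scanpy 1.11.5, anndata 0.12.19 and igraph 0.11.9, and drawn with matplotlib 3.10.9. Kept barcodes had at least 200 genes and at most 20% mitochondrial UMIs. In each library, the barcodes with the highest Scrublet scores were removed as likely doublets, at a share of 0.8% per 1000 barcodes. That removed 79 barcodes (1.30%), and 5965 of 6098 barcodes were kept. Counts were scaled to 10000 UMIs per barcode and log-transformed. The 4 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, with no batch integration and a fixed seed.

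Clusters were called X-like from 31 marker lists written before the data were examined. The scoring rule and its thresholds were set after the marker values had been seen. A marker passed where its counts per 1000000 UMIs (CPM) in the cluster, with 10 added, were at least 2-fold over the median of the other clusters and at least 25% of the cluster's barcodes had a UMI. A name needed 3 passed markers and more markers among the 10 leading genes of the cluster than any other lineage. Clusters that also carried a large part of another lineage's list stayed unnamed. A stricter form of the last condition had first left the plasmacytoid dendritic cell-like cluster unnamed, and was replaced. There were 27 clusters, of which 3 stayed unnamed. The names need not match the study's own annotation. Subtypes of T cells and of bipolar cells were compared as 1 class each.

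For each class and library, raw UMIs were summed and expressed as CPM of the class. Classes with at least 30 barcodes in both libraries were compared, days 14, 21 and 28 against day 0 for retinal classes and microglia, and days 21 and 28 against day 14 for microglia and infiltrating classes. With 1 library per day there is no replicate, so no test was made and no p-value or standard error is given. Sums carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional binomial 95% intervals. These intervals cover counting error only, not differences between mice or libraries. A gene with 0 UMIs in 1 library is given as a lower bound against a floor of 3 UMIs. Shares of barcodes with a UMI of a gene were taken after thinning each barcode to 1000 UMIs, which left out no barcode of the classes reported.

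Genes were named by a rule fixed before the data were examined. Among genes with at least 30 UMIs over the 2 libraries and 50 CPM in 1 of them, it takes the 10 highest and the 10 lowest ratios, with 0.5 UMI added, for microglia-like cells at day 14 against day 0. It takes 5 and 5 for every other comparison. Mitochondrial and ribosomal protein genes, hemoglobins, Xist and Y-linked genes, predicted gene models and antigen receptor segments were left out. So were genes at under 20% of their level in another class with at least 30 barcodes of the same library. Free RNA could supply those genes. Smaller classes could not be screened, so their leading genes could pass as named genes. Among such classes were retinal pigment epithelium-like cells on every day (Ttr and Ptgds) and neutrophil-like cells at day 14 (S100a8). Cd74, Ccl5 and examples from the fixed lists were also named, and not every gene that the rule took is printed. The share of a gene's UMIs held by the barcode with most of them was computed for each named gene.

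There were 21 gene lists, also fixed before the data were examined: antigen presentation by MHC class II and class I, type I interferon and interferon gamma responses, chemokines, inflammatory cytokines and NF-kB targets, complement, microglial homeostasis, disease-associated microglia, immediate early response, cell cycle, leukocyte adhesion and migration, T helper 1 and cytotoxic effector, T helper 17, regulatory T cell, T cell exhaustion or residency, naive or memory T cell, phototransduction, Müller gliosis and retinal stress, glycolysis and oxidative phosphorylation. For each list the median log2 ratio of its members with at least 10 UMIs over both libraries was set against 10000 random lists of the same size matched in 20 expression bins. Counts of members at least 2-fold higher or lower place genes with 0 UMIs in 1 library at their bound. Where that placement moves the median, both medians are given.

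The ratios were tested on simulated data made from the day 14 against day 0 comparison of microglia-like cells, in which 200 of 6607 genes were altered. The simulated sums were Poisson draws, the model behind the intervals, with no variation between barcodes. Coverage near 95% was therefore built in, and does not carry over to genes with most UMIs in few barcodes. In the simulation, the intervals covered the true ratio in 96.0% of genes and excluded a ratio of 1 in 4.79% of unaltered genes. They excluded a ratio of 1 in 78% of genes altered 2-fold and 98% of those altered 4-fold. Of the 20 genes with the 10 highest and 10 lowest ratios, 19 were altered ones, and 1 of 20 lists fell outside the central 95% of random lists.

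Alternatives set before the data were examined were 500 genes per barcode, mitochondrial limits of 10% or none, no doublet removal, resolutions of 0.5 and 2, variable genes chosen within libraries, ComBat adjustment by library, classes from each barcode's own markers, median-of-ratios size factors, means of per-barcode shares, subtraction of free RNA, barcodes free of T cell transcripts, a higher minimum for list members, and other thinning depths. Chosen after seeing the data were microglia-like cells without border macrophage-like barcodes, with cluster 1, or without the day 0 barcode richest in Ccl5, T cell-like barcodes with few microglial or stromal transcripts, and the use of the size factors and both resolutions for the myeloid and retinal results.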

Results

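CD45-selected cells of neuroretina were profiled at day 0 (normal retina) and at days 14, 21 and 28 after immunisation with IRBP, with 1 library per day. Per the labels, signs of uveitis peaked at day 14 and then receded. The day 0, 14, 21 and 28 libraries held 1000, 1294, 2073 and 1731 barcodes and 3039512, 6715074, 9129336 and 9530162 UMIs. Median UMIs per barcode were 2503.5, 3555.5, 3248 and 3868, the lowest were 1347, 1562, 1459 and 1887, and median genes were 1109.5, 1228.5, 1411 and 1610. Median mitochondrial shares were 5.43%, 2.74%, 2.85% and 2.88%. After filtering, 967, 1265, 2031 and 1702 barcodes remained. No value below has a replicate. Every interval is a 95% interval of counting error alone, save the spreads over members given for some list medians.

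The first question was which cells came through the bead selection over the disease course. T cell-like cells made up 0.827% of kept barcodes at day 0 (8 barcodes), 11.8% (10.1 to 13.7) at day 14, 23.8% (22.0 to 25.7) at day 21 and 25.8% (23.7 to 27.9) at day 28. Monocyte or macrophage-like cells were 0.207%, 4.19%, 10.4% and 7.23% on the same days, and conventional dendritic cell-like cells 0.103%, 3.79%, 4.78% and 3.35%. Plasmacytoid dendritic cell-like cells were 0 of 967 barcodes at day 0, which allows up to 0.310% at the floor of 3 barcodes (exact Clopper-Pearson upper bound 0.381%), and 2.06%, 2.36% and 2.53% later. Natural killer cell-like cells were also 0 at day 0, then 0.395%, 2.12% and 1.59%. Plasma or B cell-like cells, led by Jchain and Mzb1, were 0.316% at day 14, 1.28% at day 21 and 3.47% at day 28. Neutrophil-like cells were 0.103%, 0.711%, 1.53% and 0.353%. Microglia-like cells were 18.5% (16.1 to 21.1), 14.7% (12.8 to 16.8), 21.1% (19.4 to 23) and 20.2% (18.3 to 22.1) of all barcodes, which include retinal cells. Of the barcodes in leukocyte classes and cluster 1 they were 74.3%, 21.1%, 29.9% and 30.4%, or 94.2%, 66.7%, 34.4% and 33.1% with cluster 1 counted as microglia-like. A cycling class, cluster 12, led by Hist1h2ap and Top2a, held 2, 60, 25 and 9 barcodes and was not compared. The day 14 share of microglia-like cells among all barcodes was 30.7% at resolution 2 and 26.9% with classes from each barcode's own markers. Both were above the day 0 shares in those settings (22.5% and 20.8%), opposite to the direction in the main setting.

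Rod photoreceptor-like cells were 38.0% (34.9 to 41.1) of barcodes at day 0 and 12.2% (10.4 to 14.1), 18.4% (16.8 to 20.2) and 14.7% (13.1 to 16.5) later, and cone photoreceptor-like cells 19.96%, 4.66%, 6.5% and 11.5%. Bipolar cell-like cells were 6.20%, 2.85%, 1.58% and 4.11%, and Müller glia-like cells 6.51%, 1.11%, 0.689% and 2.0%. These retinal cells do not carry CD45, so bead selection, loading and the UMI cut-offs can affect the shares, and their part in the differences was not tested. Clusters 1, 2 and 11 stayed unnamed and together held 6.10%, 34.3%, 3.74% and 2.23% of barcodes at days 0, 14, 21 and 28. Cluster 1 (48, 403, 64 and 30 barcodes) was led by Saa3, C1qb and Aif1 and passed 8 of 12 microglia markers, with none among its 10 leading genes, and is compared by number. Cluster 2 mixed rod and microglial genes, and cluster 11 carried amacrine-type genes such as Slc6a9.

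**Figure D1:**
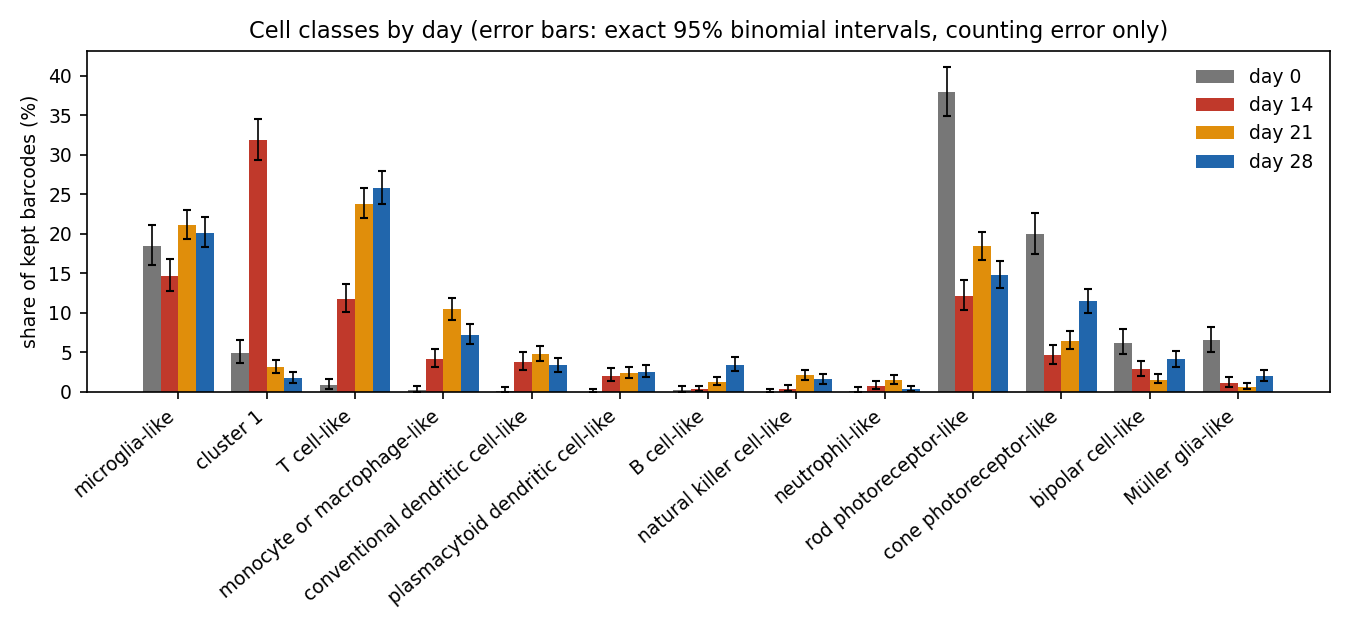
Share of kept barcodes (%) of each cell class and of cluster 1 at days 0, 14, 21 and 28, 1 library per day, with error bars of exact Clopper-Pearson 95% intervals. T cell-like cells were 0.827% at day 0 and 25.8% at day 28, while rod photoreceptor-like cells were 38.0% and 14.7%.

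The series title asks about microglia high in Cd74 and Ccl5. Cd74 (ENSMUSG00000024610, GRCm38 chromosome 18, 60803848 to 60812652, plus strand) encodes the invariant chain of MHC class II, and Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand) a chemokine that attracts T cells. In microglia-like cells Cd74 was at 1691 (1601 to 1785) counts per 1000000 UMIs of the class (CPM) at day 0, 5023 (4911 to 5137) at day 14, 5099.6 (4999 to 5202) at day 21 and 7077 (6955 to 7200.4) at day 28. It was 2.97-fold (2.80 to 3.15), 3.02-fold (2.85 to 3.20) and 4.18-fold (3.95 to 4.43) higher than at day 0. Ccl5 was at 272 (236 to 311), 2365 (2288 to 2443), 2117 (2052 to 2183) and 1944 (1880.3 to 2009) CPM, or 8.70-fold (7.57 to 10.0), 7.79-fold (6.78 to 8.99) and 7.15-fold (6.22 to 8.26) higher. Against day 14, Cd74 was 1.41-fold (1.37 to 1.45) higher and Ccl5 1.22-fold (1.16 to 1.27) lower at day 28. Ccl5 was higher at day 28 within cluster 4 (1.16-fold, 1.11 to 1.22), and cluster 3, lower in Ccl5, had 4 microglia-like barcodes at day 14 and 164 at day 28, so the class value also reflects the mix. At day 21 both stood at under 20% of their level in another class of the library. The sizes rest on few day 0 barcodes: 93.3% of the 1307 day 0 Cd74 UMIs lay in the 20 cluster 4 barcodes and 78.1% of the 210 Ccl5 UMIs in 1 barcode. Without that barcode, an alternative chosen after seeing the data, Ccl5 was 39.2-fold, 35.1-fold and 32.3-fold higher. Without barcodes with UMIs of 2 or more border macrophage markers, also chosen afterwards, Cd74 was 5.27-fold, 5.44-fold and 7.22-fold higher. Cd74 at day 14 was 7.36-fold higher with 500 genes per barcode, 6.95-fold at resolution 2, 9.68-fold with variable genes chosen within libraries and 37.9-fold with classes from each barcode's own markers, where Ccl5 was 35.6-fold higher. Ccl5 at day 14 was 15.9-fold higher when cluster 1 was included.

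Thinned to 1000 UMIs, 1.68% (0.347 to 4.82) of microglia-like barcodes had a UMI of both genes at day 0, 56.5% (49.0 to 63.7) at day 14, 28.7% (24.4 to 33.2) at day 21 and 27.7% (23 to 32.8) at day 28. Unthinned, the shares were 3.91%, 95.2%, 58.3% and 58.9%. Rod photoreceptor-like barcodes, which should lack both genes, had thinned shares of 0%, 7.79%, 2.14% and 2.39%. Median UMIs before thinning were 4190.0, 7449, 3887 and 4414 in microglia-like and 1662, 1912, 1682 and 2231 in rod photoreceptor-like barcodes. Cd74 alone was seen in 14.0%, 79.6%, 64.3% and 56.3% of thinned microglia-like barcodes and 0.817%, 26.6%, 13.1% and 11.2% of rod photoreceptor-like ones. For Ccl5 these were 3.91%, 67.7%, 38.5% and 38.5% against 0.545%, 40.3%, 16.0% and 9.96%. At day 14 a thinning depth of 500 UMIs gave 36.0% for both genes. In T cell-like cells Ccl5 stood at 5781, 9279 and 8637 CPM at days 14, 21 and 28.

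**Figure D2:**
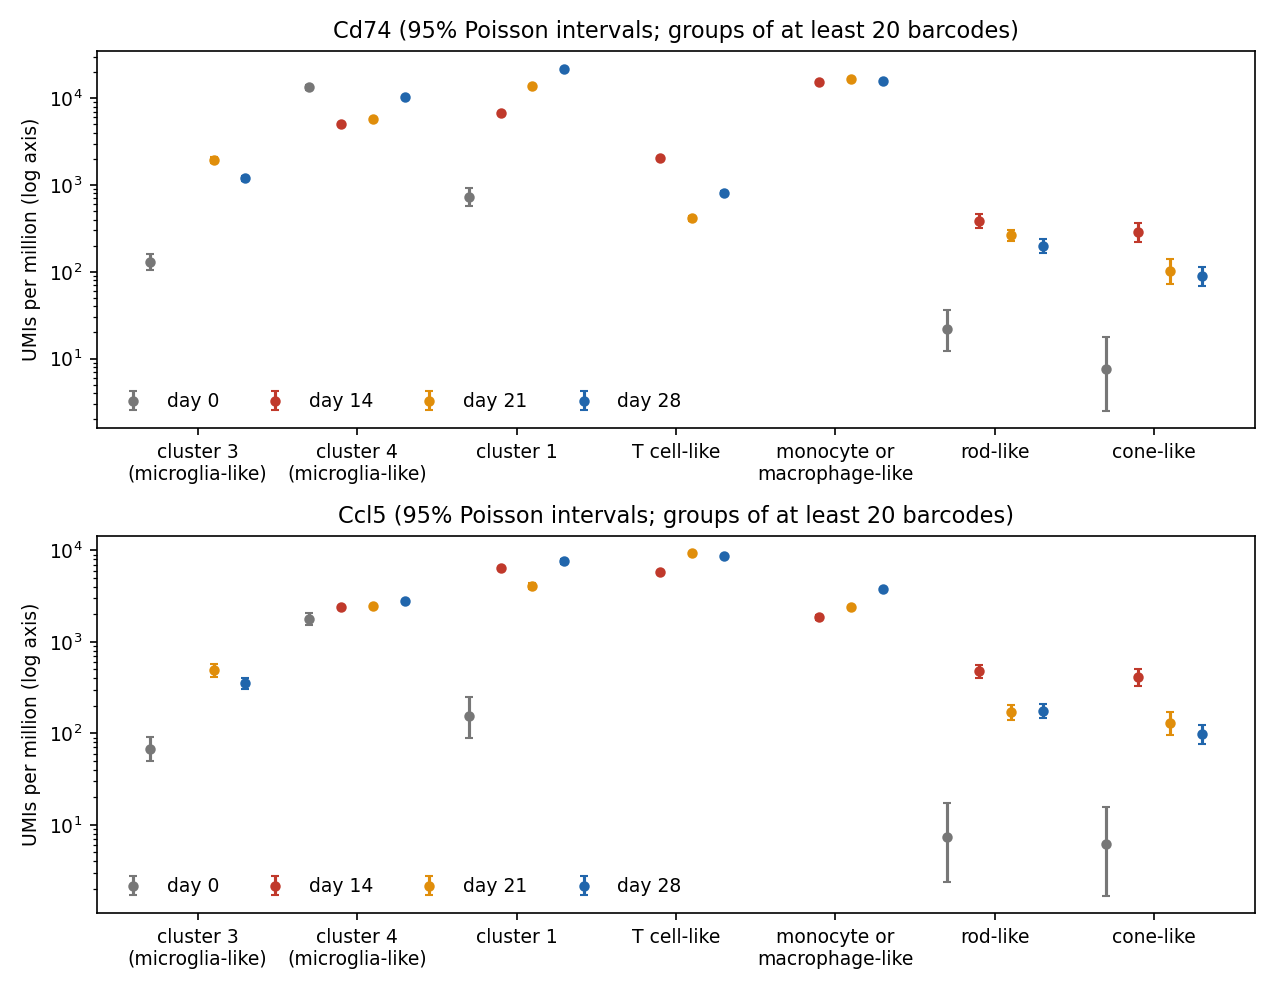
Cd74 and Ccl5 in counts per 1000000 UMIs (CPM, log axis) by day in clusters 3, 4 and 1, T cell-like, monocyte or macrophage-like, rod and cone photoreceptor-like cells, 1 library per day, groups of at least 20 barcodes, with error bars of exact Poisson 95% intervals. In cluster 4 Cd74 stood at 13316 in 20 barcodes at day 0 and at 5093 at day 14, while in cluster 3 it was 129 at day 0 and 1952 at day 21.

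**Figure D3:**
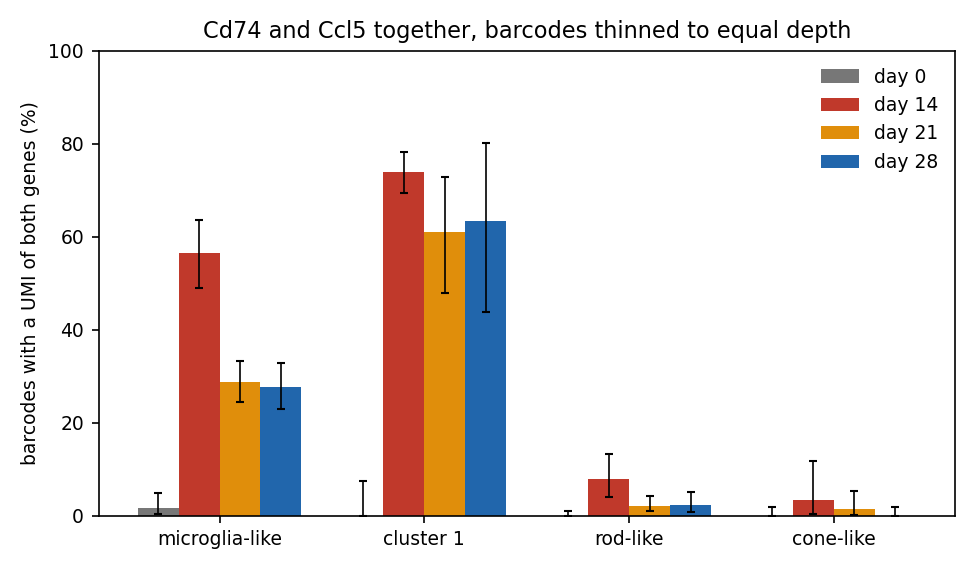
Share of barcodes (%) with a UMI of both Cd74 and Ccl5 after thinning to 1000 UMIs, by day, in microglia-like cells, cluster 1, rod and cone photoreceptor-like cells, 1 library per day, with error bars of exact Clopper-Pearson 95% intervals. The microglia-like share was 56.5% at day 14 against 7.79% in rod photoreceptor-like cells.

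Day 14 against day 0 asks what distinguished microglia at peak disease. Microglia-like cells at day 14 carried more transcript of many chemokine and interferon-inducible genes and of some complement genes, and less of many resident-microglia genes. Cxcl13, a B cell chemoattractant, had 448 against 0 UMIs (at least 76.1-fold), Ccl8, a monocyte-attracting chemokine, 242 against 0 UMIs (at least 41.1-fold), and the complement gene Cfb 210 against 0 UMIs (at least 35.7-fold). Fn1, which encodes fibronectin, was at least 31.9-fold, Il18bp, an inhibitor of interleukin 18, at least 25.5-fold, and S100a8, abundant in neutrophils, at least 16.3-fold higher. Fn1 is also on the fixed monocyte or macrophage marker list and passed as a marker of cluster 15, which carries that name. Whether such cells lay inside the microglia-like class was not tested. The neutrophil-like cluster, led by S100a8, had 9 barcodes at day 14, too few for the free RNA screen. Vcam1, an adhesion molecule for leukocytes, was 79.5-fold (14.1 to 3158) higher from 156 against 1 UMIs, and the interferon-inducible GTPases Iigp1 and Gbp2 were 38.2-fold (10.4 to 318) and 31.1-fold (14.1 to 85.2) higher. Complement C4b was 32.6-fold (15.7 to 81.5) higher. Lower at day 14 were Pf4, 60.4-fold (23 to 225), and Mrc1, 19.6-fold (7.10 to 75.6), both known markers of border macrophages, and Hpgd, which degrades prostaglandins, 22.8-fold (14.7 to 37.0). Klk8 was 13.1-fold (7.09 to 26.4) lower, Myc 8.51-fold, Lrba 8.41-fold, Gpr183 7.28-fold, Gpr155 6.34-fold, Arrdc3 6.31-fold and the heat shock gene Hspa1a 6.20-fold. A single barcode held 53.1% of the Cxcl13, 52.1% of the S100a8 and 47.5% of the day 0 Mrc1 UMIs. Barcodes with UMIs of 2 or more border macrophage markers were 7 of 179 at day 0 and 4 of 186 at day 14. Cluster 3 held 159 of 179 microglia-like barcodes at day 0 and cluster 4 held 182 of 186 at day 14.

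By the fixed lists, the interferon gamma response had the highest median log2 ratio at day 14, 2.56 (2.49 with bounds), with 14 of 18 measured members at least 2-fold higher, among them Cxcl9 (19.4-fold, 11.0 to 37.8). The type I interferon median was 1.99, with 18 of 19 members higher, including Slfn5 (21.9-fold) and Rsad2 (17.1-fold). MHC class I had a median of 1.43 with 11 of 15 higher, such as H2-Q7 (15.4-fold) and its transactivator Nlrc5 (8.91-fold). MHC class II had 0.93 with 6 of 12, such as Cd40 (3.77-fold) and H2-Ab1 (2.47-fold). The chemokine median was 1.41 with 10 of 16 higher and 2 lower, Cxcl10 being 5.31-fold higher and Ccl6 2.78-fold lower. In the complement list, at 0.66 (0.55 with bounds) with 5 of 12 higher and 1 lower, C3 was 19.4-fold and C1qa 1.15-fold higher. Inflammatory cytokines and NF-kB targets were at 0.55 with 7 of 19 higher, Il1b by 12.2-fold (9.84 to 15.3). The disease-associated microglia list was at 1.25 with 10 of 19 higher, including Fabp5 (21.8-fold), Itgax (4.73-fold) and Apoe (3.09-fold). Adhesion and migration genes were at 1.37 (0.90 with bounds). Among matched random lists, complement stood at percentile 99.96 and the other lists named so far at 100. Microglial homeostasis was at -1.24 (percentile 0), with 11 of 20 members at least 2-fold lower, such as the ADP receptor P2ry12 (4.93-fold, 4.35 to 5.61), P2ry13 (4.97-fold) and Tmem119 (2.84-fold), while Sall1 was 1.16-fold lower. The immediate early list, which tissue dissociation can induce, was at -0.69 (percentile 0).

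**Figure D4:**
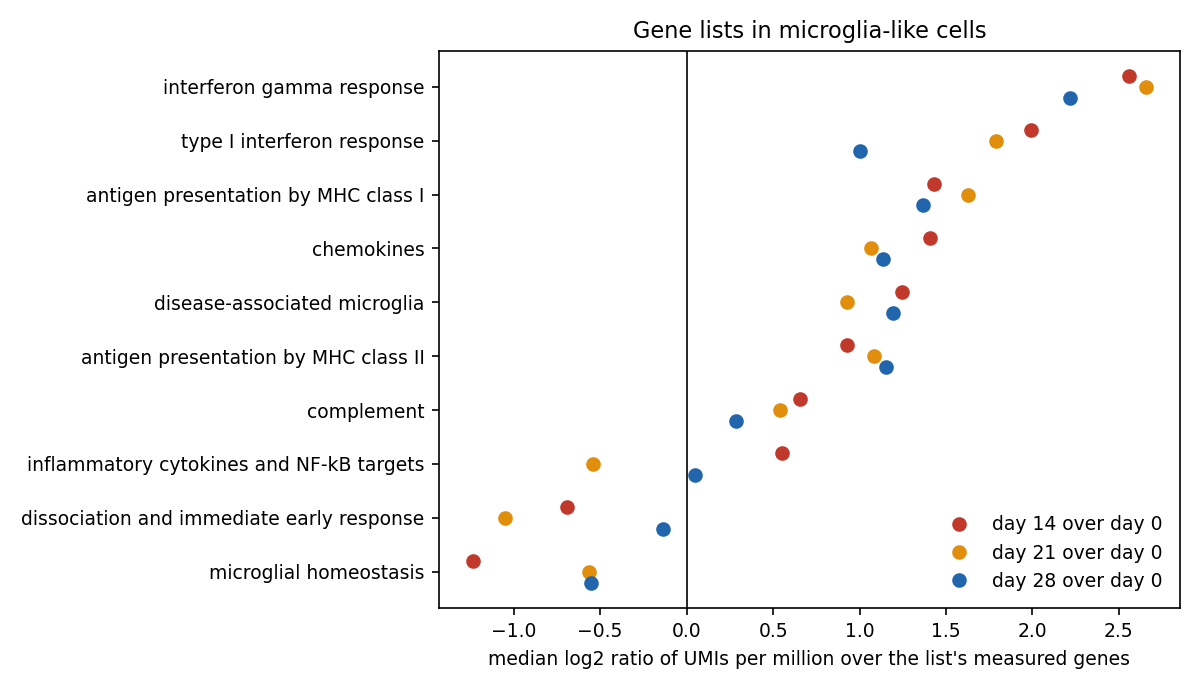
Median log2 ratio to day 0 of 10 gene lists in microglia-like cells at days 14, 21 and 28, 1 library per day, without bounds for genes at 0 UMIs. Among the lists drawn, interferon gamma response stood highest on each day (2.56, 2.66 and 2.22) and microglial homeostasis below 0 (-1.24, -0.57 and -0.55).

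Days 21 and 28 against day 0 ask what still differed after the peak. The interferon gamma median was 2.66 (2.32 with bounds) at day 21 and 2.22 (1.82 with bounds) at day 28, with Cxcl9 22.2-fold and 9.76-fold higher. MHC class II was at 1.08 and 1.15 (9 and 8 of 14 members higher), MHC class I at 1.63 and 1.37, type I interferon at 1.79 and 1.0, and disease-associated microglia at 0.93 and 1.19. Homeostasis was at -0.57 and -0.55, nearer to day 0 than at day 14, with P2ry12 2.33-fold (2.12 to 2.56) and 1.85-fold (1.69 to 2.02) lower. The day 28 median was -0.35 at resolution 2, -0.31 with variable genes chosen within libraries and -0.27 with free RNA subtracted. Cytokines and NF-kB targets were at -0.54 (percentile 0.03) and 0.05, Tnf being 1.74-fold lower at day 21 and Il1b 3.56-fold higher at day 28. The immediate early list was at -1.05 at day 21 (percentile 0, 12 of 21 members at least 2-fold lower) and -0.14 at day 28, and whether handling differed between the libraries was not tested. Complement was at 0.54 and 0.29, and chemokines at 1.07 (0.43 with bounds) and 1.14. By single genes, the highest ratios at day 21 were of Cxcl13 (at least 112-fold), Ccl8 (at least 93.7-fold, 63.0% of its UMIs in 1 barcode), Vcam1 (75.9-fold, 187 against 1 UMIs), C4b (35.2-fold) and Il18bp (at least 25.7-fold). Cxcl13 (at least 41.7-fold), Vcam1 (56.8-fold), Gpnmb, a lysosomal glycoprotein (35.0-fold, 18.4 to 76.9), Il18bp and Ccl8 led at day 28. The lowest were Pf4 (151-fold), Mrc1 (98.5-fold), Hpgd (18.5-fold), Ptgds and Klk8 at day 21, and Pf4 (20.6-fold), Ptgds (17.7-fold), Ccr1, Ttr (11.0-fold) and Hpgd at day 28. Barcodes with UMIs of 2 or more border macrophage markers, such as Pf4 and Mrc1, were 7 of 179 at day 0, 2 of 429 at day 21 and 4 of 343 at day 28. The median log2 ratio of all ranked genes was -0.19, -0.05 and -0.11 at days 14, 21 and 28 against day 0. With size factors in place of CPM, each list median of microglia-like cells that was recomputed kept its sign.

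Against day 14, the microglia-like cells of day 21 had less transcript of several inflammatory genes and more of several homeostatic genes. Il1b was 6.95-fold (6.22 to 7.78) lower, the immediate early gene Nr4a1 6.65-fold, Ptgds 6.21-fold, Cd83 5.10-fold and Apoc1 4.86-fold, while Ercc5 (4.28-fold), Arhgap5 (3.66-fold), the ERK phosphatase gene Dusp6 (3.58-fold), Kcnq1ot1 and Tmx4 were highest in ratio. The cytokine list was at -1.09 with 10 of 19 members lower, including Osm (3.62-fold) and Tnf (3.57-fold), and Cxcl10 was 3.92-fold lower. With cluster 1 included, chosen after seeing the data, the cytokine median was -0.61. Homeostasis was at 0.55 (percentile 100), with P2ry13 2.72-fold and Tmem119 2.13-fold higher. At day 28 against day 14, Gpnmb was 11.7-fold (8.83 to 15.7) higher, followed by Nsun6 (4.51-fold), Hspa1a, Otud1 and Dusp6, and Fn1 was 8.96-fold lower, with Ptgds, Apoc1, Ttr and S100a8 next. The type I interferon list was at -0.74 (5 of 20 lower, Rsad2 by 3.34-fold and Isg15 by 2.86-fold), cell cycle, with the cycling class left out, at -0.95, homeostasis at 0.70 with P2ry12 2.67-fold higher, and MHC class II at 0.38. Clusters 3 and 4 held 4 and 182 microglia-like barcodes at day 14, 86 and 343 at day 21, and 164 and 179 at day 28.

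The microglia-like clusters and cluster 1 were also compared one by one, a choice made after the clusters had been formed. In cluster 3, which held most of the day 0 microglia-like cells, Cd74 was 15.1-fold (12.1 to 19.1) higher at day 21 and 9.23-fold (7.39 to 11.6) at day 28, and Ccl5 7.22-fold (5.16 to 10.3) and 5.20-fold (3.77 to 7.31). Both genes stood there at under 20% of their level in another class. C4b was 40.4-fold and 24.5-fold higher, and the interferon gamma median was 2.20 and 1.31, while homeostasis was at -0.23 and -0.10, within the range of random lists (percentiles 7.87 and 32.9). The clusters were made from the same counts, and Tmem119, P2ry12 and Gpr34 are among the leading genes of cluster 3. Barcodes low in such genes could fall in cluster 4, so the homeostasis median within cluster 3 cannot show whether these genes returned to their day 0 level. Also high in ratio there were Cxcl13 (at least 29.1-fold), Gbp7 (15.7-fold), Cd300lf (12.6-fold) and Oasl2 (11.5-fold) at day 21 and Cxcl13 (at least 35.9-fold), H2-Q7 (10.2-fold), Cd300lf (7.61-fold) and Ccl12 (6.28-fold) at day 28, with 65.9% and 50.5% of the Cxcl13 UMIs in 1 barcode. Low were Ttr (at least 16.3-fold), Ptgds (14.9-fold), Adamts1 (8.93-fold), Mknk2 (9.71-fold) and Klk8 (9.05-fold) at day 21 and Ptgds (10.9-fold), Ttr (8.70-fold), Myc (5.31-fold), Hpgd (4.03-fold) and Fam102b (3.97-fold) at day 28. In cluster 4 Cd74 was 1.13-fold higher at day 21 and 2.0-fold (1.95 to 2.06) at day 28 than at day 14, Ccl5 did not differ detectably at day 21 (1.02-fold, 0.976 to 1.07) and was 1.16-fold higher at day 28, MHC class II was at 0.57 at day 28, and Gpnmb was 17.4-fold (13.1 to 23.4) higher. Next at day 28 were Cdo1 (11.5-fold), Gdf15 (10.8-fold), Hpse (3.68-fold) and Cpq (3.55-fold), with 60.3% of the Gdf15 UMIs in 1 barcode, and at day 21 Ercc5 (4.08-fold), Arhgap5 (3.28-fold), Kcnq1ot1 (3.06-fold), Dusp6 (2.95-fold) and Lag3 (2.85-fold). Its lowest ratios were Nr4a1 (8.82-fold), Il1b (6.52-fold), Ptgds (6.12-fold), Apoc1 (4.71-fold) and Cd83 (4.67-fold) at day 21 and Ptgds (13.7-fold), Fn1 (6.89-fold), Ttr (5.96-fold), Apoc1 (3.73-fold) and S100a8 (3.41-fold) at day 28. In cluster 1, which lacks a name, Cd74 was 9.23-fold (7.37 to 11.7) and Ccl5 41.3-fold (25.4 to 72.3) higher at day 14 than in its 48 day 0 barcodes. There Saa3, an acute phase gene, had 1879 against 0 UMIs (at least 55.8-fold), Cxcl9 was at least 15.9-fold higher, and Cst3 was 6.45-fold (6.26 to 6.64) and Hpgd 12.3-fold lower. Ccl8 (at least 9.89-fold), Ly6i (at least 9.41-fold) and Cxcl13 (at least 7.48-fold) were also higher, and Pf4 (14.6-fold), Serpine2 (6.22-fold) and Ltc4s (6.16-fold) lower. Its MHC class II median was 1.53 (1.13 with bounds), its interferon gamma median 1.87 (1.23 with bounds) and its homeostasis median -1.06.

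T cell-like cells were compared from day 14 on, since day 0 held 8. Some cytotoxic genes were higher after the peak: at day 21 Gzmb was 3.04-fold (2.49 to 3.72), Gzmk 2.25-fold (1.80 to 2.84) and Ccl5 1.61-fold (1.56 to 1.65) higher than at day 14, and at day 28 Cd8a was 4.69-fold (3.62 to 6.17), Gzmb 1.957-fold (1.60 to 2.41) and Ccl5 1.49-fold (1.45 to 1.54) higher. The T helper 1 and cytotoxic list was at 0.69 and 0.52 (2 and 3 of 16 members at least 2-fold higher, percentiles 100 and 100), and at 0.43 and 0.07 at resolution 0.5. The mix of clusters in the class differed between days: cluster 14, led by Nkg7, Gzma and Cd8b1, held 20 of 149, 107 of 484 and 133 of 439 barcodes at days 14, 21 and 28, cluster 25, led by Tnfrsf4 and Tnfrsf18, 12, 57 and 62, and cluster 18 the other 117, 320 and 244. The median over all ranked genes was itself 0.23 at day 21 and 0.06 at day 28. The regulatory T cell list was at 0.59 and 0.67 (percentiles 99.5 and 99.98). At day 21 the spread over members included 0 for the cytotoxic (-0.35 to 0.99) and the regulatory (-0.05 to 1.08) list. Among regulatory genes, Foxp3, the regulatory T cell transcription factor, was 2.07-fold and 2.18-fold higher, and Il2ra 2.14-fold at day 21. The naive or memory list was at 0.55 and 0.65 (percentiles 98.9 and 99.96), with Il7r 2.13-fold and 1.74-fold higher. In the T helper 17 list, at 0.10 and 0.40 (percentiles 25.7 and 90.9), Ccr6 was 3.77-fold higher at day 21 while Il17a did not differ detectably at day 28 (1.05-fold, 0.753 to 1.48). Exhaustion or residency genes were at 0.07 and 0.03 (percentiles 21.6 and 32.9). Among single genes at day 28, Xcl1 (12.7-fold, 43.2% of its UMIs in 1 barcode), Klre1 (4.92-fold), Klrk1 and Klrc2, genes of cytotoxic lymphocytes, led with Cd8a. Xcl1, Klre1 and Klrk1 are also leading genes of the natural killer cell-like cluster. Its 27 day 28 barcodes were too few for the free RNA screen.

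The genes lowest in T cell-like cells after day 14 were ones of other cells, such as Ptgds (27.0-fold at day 21), Ttr (19.1-fold and 11.2-fold), Apoc1 (22.2-fold and 24.6-fold) and Aif1 (11.1-fold and 8.93-fold), with Cd63 at day 21 and Crybb1 and Trf at day 28. The median share of 7 microglial genes in T cell-like barcodes was 0.941% at day 14, 0.175% at day 21 and 0.156% at day 28, and 74 of 149, 39 of 484 and 41 of 439 barcodes exceeded 1%. The medians of MHC class II (-1.92 and -1.21), complement (-2.54 and -2.19) and chemokines (-2.04 and -1.39) were lower on the days when that share was lower, and Cd74 was 4.90-fold and 2.5-fold lower. Without barcodes over 1%, chosen after seeing the data, MHC class II was still at -1.45 and -0.85, the cytotoxic median was 0.32 and 0.12 and the regulatory one 0.18 and 0.51. The highest ratios at day 21, of Dcn, Mgp, Cldn5, Vwf and Apod, came almost wholly from a single barcode (100% of the Dcn and 98.4% of the Cldn5 UMIs).

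The comparison of monocyte or macrophage-like cells asked how infiltrating myeloid cells differed after the peak. At day 21 many of their inflammatory genes were lower than at day 14: Il1b was 5.26-fold (4.91 to 5.65), Il6 7.42-fold (4.78 to 11.7), Ptgs2, which encodes the prostaglandin synthase COX-2, 7.82-fold and the chemokine gene Cxcl1 9.92-fold lower. The cytokine and NF-kB list was at -1.07 with 10 of 18 members lower, and its spread over members included 0 (-1.695 to 0.015). At resolution 2, an alternative chosen after seeing the data, the list was at -0.27. It was at -0.38 at day 28, when Il1b was 2.34-fold and Il6 7.29-fold lower. The nonclassical MHC class I gene H2-M2 was 22.4-fold (7.56 to 109) and 23.6-fold (7.94 to 115) higher, Cxcl9 6.02-fold (4.58 to 8.06) and 6.32-fold (4.80 to 8.48), and Serpina3g 4.2-fold at day 21, where the interferon gamma list was at 0.58. Cd74 stood at 15554, 16631 and 15880.3 CPM, and Ccl5 was 2.03-fold (1.89 to 2.17) higher at day 28. Cdo1 (32.7-fold, 84 against 1 UMIs), the lectin gene Mgl2 (12.7-fold), Dnase1l3 (10.2-fold) and Cd8a (10.2-fold) were also high in ratio at day 28. Lowest were Ptgds (29.6-fold), Ttr and Ccl8 at day 21, and Ccl8 (56.8-fold), Ttr, Il6, Ptgds and Thbs1 at day 28. The T helper 1 and cytotoxic list was at 1.27 (1.05 with bounds) at day 28 (9 of 15 members higher), and several of its members, such as Nkg7, stood at under 20% of their T cell-like level. At day 21 the ratios of Hspa1b, Hspa1a and Lyz1 rested on 1 barcode (98.2%, 92.1% and 74.5% of their UMIs). Cluster 15 held 51, 189 and 111 of the barcodes at days 14, 21 and 28 and cluster 21 the other 2, 23 and 12. Microglial genes exceeded 1% in 49 of 53, 145 of 212 and 82 of 123 barcodes.

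Conventional dendritic cell-like cells had more transcript of several MHC class II genes after the peak. Cd74 was 2.5-fold (2.42 to 2.58) higher at day 21 and 1.91-fold (1.85 to 1.98) at day 28, H2-Ab1 2.85-fold (2.70 to 3.0) and 2.22-fold (2.1 to 2.35), and the class II transactivator Ciita 3.61-fold at day 21. The MHC class II list was at 0.91 and 0.63 (6 and 3 of 14 members higher). Ccl17, a ligand of CCR4, was 5.15-fold (4.2 to 6.39) higher at day 21, and the lectin genes Mgl2 and Clec10a 5.76-fold and 4.48-fold. Anpep was 10.5-fold higher from 40 against 2 UMIs, and Gzma 44.7-fold at day 28 from 63 against 1 UMIs. Gzmk (10.5-fold) at day 21, and Tnfsf8 (33.3-fold), Xcl1 (29.8-fold) and Nrgn (16.3-fold) at day 28, were also high in ratio, each of the last 3 with 1 to 4 UMIs at day 14. Gzma and Xcl1 are leading genes of the natural killer cell-like cluster, whose 27 day 28 barcodes were too few for the free RNA screen. Cell cycle genes, with the cycling class left out, were at -0.68 and -0.99, and immediate early genes at 0.99 at day 28, Fosb being 4.96-fold higher. Lower were Apoc1 (32.3-fold) and Hmox1 (8.40-fold) at day 21, and Cd209d (at least 14.6-fold), S100a8 (53.6-fold) and S100a9 (27.7-fold) at day 28, with Ttr lower on both days (10.6-fold and 13.2-fold). The low ratios of Ccl1 and Ly6d at day 21 rested on 1 day 14 barcode (97.4% and 95.2% of their UMIs). Cluster 22, led by Ccr7 and Ccl22, held 29, 41 and 23 of these barcodes at days 14, 21 and 28 and cluster 23, with Ccl17, H2-Eb1, H2-Ab1 and H2-Aa among its leading genes, held 19, 56 and 34, so the mix of the clusters differed between days. Plasmacytoid dendritic cell-like, natural killer cell-like, plasma or B cell-like and neutrophil-like cells had under 30 barcodes on 1 or both days and were not compared.

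The comparison of rod photoreceptor-like cells asked what neurons of the inflamed retina showed. Some stress genes were higher on the later days: Gadd45b was 12.7-fold, 13.4-fold and 14.5-fold higher, the growth factor gene Fgf2 7.23-fold (3.02 to 19.9), 3.20-fold (1.34 to 8.79) and 4.53-fold (1.956 to 12.2), and Edn2, an endothelin induced in stressed photoreceptors, 25.6-fold (6.77 to 217) at day 21 and 33.2-fold (8.84 to 280.2) at day 28. The gliosis and retinal stress list was at 2.81, 1.66 and 1.47, with 8 of 8, 7 of 9 and 5 of 8 members higher. The fixed list includes genes of glia, such as Gfap, and a part of free RNA in its medians was not tested. Of the genes within the UMI and CPM limits, 73 at least 2-fold higher at day 14 stood at under 20% of their level in another class. Irf9 was 19.0-fold (5.84 to 97.8) higher at day 14. Phototransduction genes were at -0.35, -0.11 and 0.03, with none of 20 members 2-fold lower at day 14, when Pdc was 1.77-fold (1.69 to 1.85) lower. Unc119 was 3.0-fold (2.83 to 3.18) lower at day 21. Cluster 8, which has Unc119 among its leading genes, held 182 of 367, 35 of 154, 52 of 374 and 12 of 251 rod photoreceptor-like barcodes at days 0, 14, 21 and 28, and cluster 5 the rest, so the mix of the clusters differed between days. Ttr (16.4-fold at day 21 and 13.3-fold at day 28) and Ptgds (30.6-fold and 10.1-fold) were the lowest. Also low were Sp3os (4.56-fold), Prpf8 (3.50-fold), Ttr (3.40-fold), Plcxd2 (3.41-fold) and Ccdc63 (3.32-fold) at day 14, Btbd2 (4.96-fold) and Mtch1 (3.27-fold) at day 21 and Cd2bp2 (3.8-fold), Sbk1 (3.02-fold) and Abhd17a (2.93-fold) at day 28, and high were Jchain (4.50-fold), Lrrc2 (4.26-fold) and Rnpc3 (4.02-fold) at day 21 and Pcolce (6.31-fold), Ppargc1b (4.94-fold) and Lrrc2 (4.76-fold) at day 28. Jchain leads the plasma or B cell-like cluster, whose 26 day 21 barcodes were too few for the free RNA screen. The MHC class I list was at 3.8, 2.82 (2.71 with bounds) and 3.0 (2.84 with bounds) and MHC class II at 3.29, 2.73 and 2.44, but H2-K1, H2-D1 and B2m, 21.1-fold, 10.8-fold and 10.6-fold higher at day 14, stood at under 20% of their level in a leukocyte class, where free RNA could supply them. The median share of microglial genes in rod photoreceptor-like barcodes was 0.611%, 0.909%, 0.521% and 0.487%. It exceeded 1% in 30 of 367, 59 of 154, 23 of 374 and 14 of 251 barcodes at days 0, 14, 21 and 28. Cd74 (17.6-fold, 11.9-fold and 9.0-fold higher) and Ccl5 (64.6-fold, 23.1-fold and 23.9-fold) also stood at under 20% of their level in another class on all 3 days. The ratio of Mt2 at day 14 rested on 1 barcode (93.7% of its UMIs).

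In cone photoreceptor-like cells MHC class I genes were the highest in ratio at day 14 once genes with under 30 UMIs and genes at under 20% of their level in another class, such as Ccl5 and Cd74, were set aside. Those named here for that day stood above 20% of their level in every other class with at least 30 barcodes. H2-Q7 was 83.5-fold (27.6 to 413), H2-K1 28.1-fold (19.0 to 43.1), H2-D1 19.5-fold (15.1 to 25.5), H2-Q6 10.1-fold and H2-Q4 6.33-fold higher than at day 0. The list, of which 13 of 13 members were higher, was at 4.32, 3.01 and 2.14 at days 14, 21 and 28. At day 28 H2-K1 was 7.89-fold (5.32 to 12.1) higher, then at under 20% of its level in another class. The homeodomain gene Hopx was 3.81-fold (2.71 to 5.41) and 4.37-fold (3.22 to 6.04) higher at days 21 and 28, and phototransduction was at -0.45, -0.36 and -0.12. Other high ratios were Ofd1 (3.58-fold), Fam21 (3.41-fold) and H2-Q4 (3.33-fold) at day 21 and Cse1l (3.26-fold), Txndc16 (2.68-fold), Cldnd1 (2.67-fold) and Klhdc1 (2.61-fold) at day 28, and Hspa1a at day 21 had 74.3% of its UMIs in 1 barcode. Low were Ptgds (6.52-fold), Doc2b (5.67-fold), Dll1 (4.12-fold), Por (4.12-fold) and Fmr1 (3.95-fold) at day 14, Ttr (26.8-fold), Ptgds (13-fold), Rtn2 (7.44-fold), Mafg (5.38-fold) and Acvr2b (5.28-fold) at day 21 and Ttr (17.7-fold), Ptgds (17.1-fold), Abhd17a (2.70-fold), Bod1 (2.61-fold) and Strn4 (2.51-fold) at day 28. Cd74 was 37.9-fold, 13.3-fold and 11.6-fold higher and Ccl5 67.0-fold, 21.3-fold and 16.0-fold, all at under 20% of their level in a leukocyte class. Cluster 10 held 34 of 193 cone photoreceptor-like barcodes at day 0 and 1, 1 and 0 later, and cluster 0 the others.

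In the 36 bipolar cell-like barcodes of day 14 H2-K1 was 77.0-fold (90 against 2 UMIs), H2-Q7 at least 18.3-fold, Clu 3.85-fold and Scgn 3.72-fold higher. The MHC class I medians were 4.85 (3.76 with bounds), 3.50 and 2.72 on the 3 days. H2-K1 and H2-Q7 passed the free RNA screen at day 14. Of the genes within the UMI and CPM limits, 22 at least 2-fold higher at day 14 did not pass. Cd74 and Ccl5 did not pass on any of the 3 days, so free RNA could supply them. A part of free RNA in the MHC class I medians was not tested. Clusters 7, 13 and 17 held 42, 4 and 14 bipolar cell-like barcodes at day 0, 22, 5 and 9 at day 14, 14, 2 and 16 at day 21, and 37, 6 and 27 at day 28, and Scgn and Cck are among the leading genes of cluster 13. Cck (2.92-fold) followed at day 14, Gucy1a3 (4.35-fold), App (4.18-fold), Nfib (4.10-fold), Snhg11 (3.34-fold) and Scgn (3.29-fold) were highest in ratio at day 21, and Samsn1 (3.85-fold), Ptprz1 (3.61-fold), Eml5 (3.26-fold) and Sptan1 (3.09-fold) at day 28. Low were Stom (4.26-fold), Man2a2 (3.0-fold), Robo2 (3.04-fold), Slco5a1 (3.04-fold) and Kif22 (2.84-fold) at day 14, Ttr (at least 4.03-fold), Cadm4 (15.4-fold), Pcif1 (6.04-fold), Abhd17a (5.06-fold) and Mtch1 (4.76-fold) at day 21 and Ttr (9.71-fold), Abhd17a (3.18-fold), Tmbim1 (3.24-fold) and Adrb1 (3.09-fold) at day 28.

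Müller glia-like cells could be compared at day 28 against day 0, with 34 and 63 barcodes, while days 14 and 21 held 14 each. Lcn2, a siderophore-binding lipocalin of the acute phase, had 3715 against 1 UMIs, or 21307 against 4.38 CPM, from 10 barcodes at day 28. It is also a leading gene of the neutrophil-like cluster, whose 6 day 28 barcodes were too few for the free RNA screen. Some complement genes were also far higher, C3 by 207-fold (57.0 to 1721), Cfb by at least 90.3-fold, Serping1 by 44.8-fold (18.8 to 139.7) and C4b by 47.1-fold (12.6 to 397). The complement median was 5.25 with 4 of 7 members higher and 3 lower, the microglial gene C1qa among the lower. MHC class I was at 2.91 with 12 of 14 higher, including H2-K1 (9.86-fold, 7.16 to 13.9) and B2m (7.05-fold, 5.90 to 8.49), MHC class II at 2.39 (2.24 with bounds), interferon gamma at 3.15 (2.29 with bounds) with 10 of 10, and gliosis and stress at 0.95, while Vim did not differ detectably (1.08-fold, 0.830 to 1.41). Ttr (12.7-fold), Klf4 (11.1-fold, 58.6% of its day 0 UMIs in 1 barcode), Mxi1 (9.36-fold), Tmed5 and Spred1 were the lowest. A single barcode held 97.2% of the Saa3 and 78.3% of the Ifitm1 UMIs. Cd74 was 5.83-fold and Ccl5 238-fold higher, at under 20% of their level in another class, with 79.1% of the Ccl5 UMIs in 1 barcode.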

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

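The test of UMIs per barcode was written before its result was seen, and the other tests in this part were chosen only after the results were seen, as was the limit of 0.3 on list medians. List medians that lay outside 95% of random lists on 2 days, with opposite signs, drew attention, and none of these differences between days was tested. In microglia-like cells, inflammatory cytokines and NF-kB targets were at 0.55 at day 14 and -0.54 at day 21 against day 0, with a spread over members that included 0 on both days (-0.05 to 1.30 and -0.85 to 0.16). The immediate early list, which dissociation can induce, was at -0.69 and -1.05 on those days. In rod photoreceptor-like cells, complement was at 2.20 at day 14 and 0.67 at day 21 but -0.34 at day 28, on 3 or 4 members such as C1qa and C1qb. Both are microglial genes. The median share of microglial genes in rod photoreceptor-like barcodes was 0.611%, 0.909%, 0.521% and 0.487% at days 0, 14, 21 and 28. On the same days it exceeded 1% in 30 of 367, 59 of 154, 23 of 374 and 14 of 251 barcodes. Whether free RNA gave these complement values was not tested. T helper 1 and cytotoxic genes in the same cells were at 1.57 at day 14 and -0.98 at day 28. In cone photoreceptor-like cells that list was at 0.75 at day 14, -0.74 at day 21 and -1.11 at day 28, with Ccl3, Ccl4 and Ccl5 among its few members.

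Ccl5 in microglia-like cells stood higher at each later day than at day 0. Free RNA of T and natural killer cells, as the whole cause, would give photoreceptor-like cells a like level, but microglia-like cells held at least 5.28 times (4.64 to 6.04) the Ccl5 CPM of photoreceptor-like cells of the same library, the lowest of the 3 days. Barcodes shared with a lymphocyte would bring Cd3e, Cd3d, Cd3g, Nkg7 and Ctsw in proportion, but Ccl5 per UMI of those genes was at least 4.98 times (4.45 to 5.58) that of T cell-like and natural killer cell-like cells. Neither excludes a contribution of some free RNA, and differences between single mice or libraries cannot be told apart from the day. Induction of Ccl5 in microglia during the disease stays open as a hypothesis, found and tested on the same data.

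At day 0, Cd74 and Ccl5 of microglia-like cells lay in few barcodes, which sets the folds of every later day. Barcodes with UMIs of 2 or more border macrophage markers, such as Mrc1 and Pf4, held 47.7% (45 to 50.5) of the day 0 Cd74 UMIs, a value between the bounds of 25% and 50% that would have decided, so border macrophages inside the class may account for part of it. A single barcode with none of those markers held 78.1% (71.9 to 83.5) of the day 0 Ccl5 UMIs, so the day 0 Ccl5 level is largely that of 1 barcode. Whether normal retina holds a rare Cd74-rich and Ccl5-rich cell cannot be read from 1 barcode.

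Cluster 1, with Saa3, C1q genes and microglia markers, came mostly from the day 14 library. With 589 day 14 barcodes thinned to 1562 UMIs, 80.3% of the neighbours of cluster 4 barcodes were of cluster 4, against 30.9% by size and 95.4% unthinned. This argues against fewer UMIs per barcode as the whole cause of the separation of cluster 1 from cluster 4. The cluster labels came from the full counts of the same barcodes, so part of the 80.3% was built in. Damaged cells remain possible, since the median mitochondrial share was 1.15 times that of cluster 4 (2.46% against 2.14%), which decides neither way. A contribution of free RNA to these droplets also stays open. A microglial state of peak disease and an effect of that 1 library cannot be told apart, because no other library was made at day 14.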

How the results depend on the processing

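Recomputing the results under the other settings gave 346 values, of which 277 stayed within the interval of the value reported, 69 moved beyond it and 0 were scored as reversed. A reversal could be scored only for ratios and list medians whose reported interval excluded no difference, never for shares. The interval of the value reported is counting error for shares and ratios, but for list medians it is the wider spread over list members, so a median inside it can still have moved by much. Those chosen after seeing the data are the values without border macrophage-like barcodes, with cluster 1, without the richest Ccl5 barcode and for the T cell-like subsets, and the size factors and resolutions used for the myeloid and retinal results. Ratios below are over day 0 and for microglia-like cells, in the order of days 14, 21 and 28 where 3 are given, and the cause was not tested for any value below. No value left its interval with size factors (14 values), means of per-barcode shares (7), list members with at least 30 UMIs (4) or T cell-like barcodes with under 1% stromal genes (6).

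The microglia-like share at day 0 was 21.7% with 500 genes per barcode, 26.4% with a 10% mitochondrial limit, 22.9% with no limit, 22.5% at resolution 2, 21.5% with variable genes chosen within libraries and 21.9% after ComBat. At day 14 it was 17.9% with no mitochondrial limit, 17.6% with no doublet removal, 30.7% at resolution 2 and 26.9% with classes from each barcode's own markers, and at day 28 16.4% with variable genes within libraries. At resolution 2 and with each barcode's own markers, the day 14 share was above that of day 0 (22.5% and 20.8%). That is opposite to the direction reported. The T cell-like share at days 21 and 28 was 19.2% and 18.3% at resolution 0.5, and 26.5% and 28.4% with variable genes within libraries.

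The Cd74 ratio was 7.36, 7.58 and 10.5 with 500 genes, 3.22, 3.22 and 4.44 with a 10% mitochondrial limit, 6.95, 7.0 and 9.95 at resolution 2, 9.68, 10.1 and 14.9 with variable genes within libraries, and 37.9, 35.6 and 52.8 with classes from each barcode's own markers. It was 5.27, 5.44 and 7.22 without border macrophage-like barcodes, 3.67, 3.63 and 5.02 with cluster 1, and 3.87, 3.92 and 5.45 without the richest Ccl5 barcode. With no mitochondrial limit it was 3.19 at day 14 and 4.81 at day 28, and without T cell gene UMIs 3.92 at day 28. The Ccl5 ratio was 35.6, 25.4 and 31.0 with classes from each barcode's own markers, 39.2, 35.1 and 32.3 without the richest barcode, and 7.26, 6.51 and 5.45 without T cell gene UMIs. At day 14 it was 10.1 with a 10% mitochondrial limit, 10.2 at resolution 2 and 15.9 with cluster 1, and at day 28 8.98 with no doublet removal and 8.83 with cluster 1.

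The share with both genes was 36.0%, 17% and 20.7% when thinned to 500 UMIs and 95.2%, 58.3% and 58.9% unthinned, and more UMIs per barcode raise such shares by construction. At day 14 it was 48.1% with a 10% mitochondrial limit and 68.4% with cluster 1, and at day 28 34.1% with no doublet removal. The homeostasis median at day 28 was -0.35 at resolution 2, -0.31 with variable genes within libraries and -0.27 with free RNA subtracted, and the cytokine median at day 21 against day 14 was -1.54 with free RNA subtracted. List medians inside that spread but over 1.5 times smaller than reported include the cytokine median of microglia-like cells at day 21 against day 14 with cluster 1 (-0.61), that of monocyte or macrophage-like cells at resolution 2 (-0.27). In T cell-like cells against day 14 they include the cytotoxic median at resolution 0.5 (0.43 at day 21 and 0.07 at day 28), the MHC class II median at day 28 with variable genes within libraries (-0.78), and with under 1% microglial genes the cytotoxic (0.32 and 0.12) and day 21 regulatory (0.18) medians. Microglia-like cells with no UMI of the T cell, neutrophil and rod genes were too few to give a value.

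No paired analysis was possible because each day had 1 library and the labels pair no mice. Depth limits genes with few UMIs: with 0 UMIs in 1 library only a bound on the fold is known, and classes with under 30 barcodes gave no comparison.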

Other observations

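In microglia-like cells at day 14, lists of energy metabolism had medians above those of most random lists, with few members differing by 2-fold. Against day 0, oxidative phosphorylation was at 0.50 at day 14 (percentile 99.2, 2 of 15 members at least 2-fold higher) and glycolysis at 0.43 (percentile 99.5, 1 of 14). Against day 14, oxidative phosphorylation was at -0.31 at day 21 (percentile 3.22, inside the central 95% of random lists) and -0.45 at day 28 (percentile 0.185), and glycolysis at -0.25 (percentile 2.8, also inside) and -0.41 (percentile 0.07). Cell cycle genes in microglia-like cells were at 0.32 at day 14 against day 0 (percentile 99), a median that leaves out the cycling class of 2 barcodes at day 0 and 60 at day 14.

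Ttr and Ptgds, the leading genes of the retinal pigment epithelium-like cluster, were lower after day 0 in several other classes. Ttr was 11.0-fold lower at day 28 in microglia-like, 13.3-fold in rod photoreceptor-like and 12.7-fold in Müller glia-like cells, and that cluster was 2.17%, 0.870%, 0.295% and 0.353% of barcodes at days 0, 14, 21 and 28. In microglia-like cells at day 28 against day 0 the regulatory T cell list was at 1.79 (1.20 with bounds) and the T helper 1 and cytotoxic list at 3.07 (1.10 with bounds), where the T cell-like share of barcodes was 25.8%. The photoreceptor genes of the phototransduction list in microglia-like cells were at -0.85, -0.83 and -0.54 at days 14, 21 and 28, where the rod photoreceptor-like share was 12.2%, 18.4% and 14.7% against 38.0% at day 0.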
